A study of Mus musculus with 8 samples.

How the data were processed

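Gene expression was measured in hypothalamus and liver of male mice of 2 strains under 2 diet conditions. The strains were C57BL/6J, called B6 here, and B6.CAST-17, a homozygous congenic strain that carries a CAST donor segment of chromosome 17 on the B6 background. The diet conditions were chow and a choice between a carbohydrate/protein and a fat/protein diet, each with 78% of the main macronutrient and 22% protein, called 2-choice here. Per the labels, 20 to 25 mice of each strain had been tested for self-selection over 10 days, the mice most divergent in nutrient intake were kept, returned to chow for 6 weeks and then given the choice for 1 day, and tissues were taken 4 h before lights out. That time was recorded here for the 2-choice samples only, so the collection time of the chow samples was not established here. Each of the 8 samples was RNA pooled from 6 mice, so each combination of tissue, strain and diet had 1 array and there were no replicate pools.

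Per the labels' protocols, total RNA was purified with an organic reagent and columns, and 1 microgram was transcribed into digoxigenin-labelled cRNA with a chemiluminescent kit of Applied Biosystems, for single-channel arrays. The deposited values were linear probe intensity for 33012 probes, with no missing value and none at or under 0. The authors' background correction and normalization are not given in the sources used here, and detection flags were not used here. In the deposited table, the sorted intensities of the 2 strains of each tissue and diet agreed within 0.244%, so each such pair had been brought to a common distribution by the authors. The pairs differed from each other: the median intensity was 560 for both hypothalamus chow arrays, 1338 for both hypothalamus 2-choice arrays, 700 for both liver chow arrays and 702 for both liver 2-choice arrays. The largest gap between quartiles within a tissue was 2.23 on the log2 scale in hypothalamus and 0.0928 in liver. Each strain comparison therefore lies inside 1 scaling set, while each diet comparison crosses 2 sets, and diet and scaling set cannot be told apart.

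Groups came from the sample titles, which match the strain, tissue and diet characteristics. Some free-text descriptions differ from the titles: that of the hypothalamus congenic chow sample names C57BL/6J, those of the liver samples name hypothalamus, and those of the liver chow samples name the 2-choice diet. Levels of tissue marker genes were given for every array as a check of the tissue. Values were taken to log2 and, under the rule set for tables whose arrays differ by over 0.1, quantile normalized over the 4 arrays of a tissue. Probes with a mean log2 level at or above the 40th percentile of their tissue were tested, which left 19807 in each tissue and 15466 in both.

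Effects were fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a trend on mean level), with Benjamini-Hochberg adjustment over the probes tested and a threshold of 0.05. The effects over both tissues used 4 matched pairs as blocks (3 residual degrees of freedom). The effects per tissue and the interactions with tissue came from 1 fit of all 8 arrays with terms for tissue, strain within tissue and diet within tissue (2 residual degrees of freedom). In both designs the error is made of interactions, since no pool was repeated, and the p-values measure only the spread between these pools. Strain by diet within a tissue has no error term and is given as values. A fit on the 4 arrays of a tissue alone (1 residual degree of freedom), other scalings, filters, variance models and leaving out each array or pair were run as alternatives. On simulated data with real probe levels and 100 probes changed at each size, the strain fit over both tissues recovered 35 at a log2 change of 1 and 72 at 2, with 10 false calls. The strain fit within liver recovered 12 and 50 with 17 false calls, and that within hypothalamus 8 and 38 with 4. The diet fit within hypothalamus recovered 17 and 47 with 8 false calls, and that within liver 18 and 50 with 17. The simulated noise was normal, independent and of equal spread on all 8 arrays, taken from the fit's own variances. The real hypothalamus pairs differed in spread, so these counts describe the model and not the real arrays.

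The 40 gene lists (pathways, gene families and cell type markers), the designs and the rule for named genes were fixed before the data were examined. Lists were tested with camera (preset inter-gene correlation of 0.01), with adjustment over the lists of a comparison, and again with an estimated correlation and with fry. The rule named, per main comparison, up to 15 higher and 15 lower called genes that went the same way in every matched pair. Where fewer than 10 probes were called, it named the 10 higher and 10 lower genes with the largest change among those with a mean change of at least 1.5-fold and the same sign in every pair, given as values that did not pass. The rule as written can also be read as 1.5-fold in each pair, which 6 of the 20 genes so named for strain over both tissues met, 14 of 20 for strain in hypothalamus, 18 of 20 for strain in liver and 19 of 20 for diet in liver. It added up to 4 members of each list described, the 5 highest and 5 lowest single-pool differences, and Glo1, Glp1r, Decr2 and Agpat1. Genes called only in an alternative fit fall outside the rule and were chosen after their values were seen.

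Of the probes, 14411 carried 1 gene symbol in the platform annotation (13840 genes), 247 carried several and 18354 none. Probes with several symbols or none were counted, not named, and the probe with the highest mean level stood for a gene. Symbols and chromosomes of 14402 probes were updated through Entrez identifiers in RefSeq's table for GRCm38.p6. Chromosome 17 was divided into bins of equal length by gene start in that table, and the bins are named by their end genes. The build behind the array design is not given in the sources used here, so coordinates of the bins are not printed. Genes counted as apart on a chromosome had a mean difference of at least 1.5-fold and the same sign in every pair of the set, and 1.5-fold in each pair was an alternative added after the data were seen. The share of chromosome 17 was tested with Fisher's exact test, two-sided, over genes with a known chromosome. Probe sequences were not analysed here, so a base difference of the donor segment under a probe would enter these values as a difference in level. The number of arrays limits the precision of every value. Plots were drawn with matplotlib 3.10.9.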

Results

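The data held 8 single-channel arrays, each read from 1 pool of RNA of 6 male mice: hypothalamus and liver of B6 and B6.CAST-17 congenic mice, on chow or after 24 h with a choice of diets. The tissue markers matched the tissue labels on every array. The log2 level of Alb, the albumin of hepatocytes, was 20.07 to 21.40 in the liver arrays and 8.75 to 11.42 in the hypothalamus arrays. Apoa1, a lipoprotein component made in liver, was 19.68 to 19.95 against 8.84 to 11.12. Hcrt, the orexin precursor of the lateral hypothalamus, was 14.48 to 15.98 in hypothalamus and 8.22 to 8.89 in liver, and the vasopressin gene Avp was 15.92 to 16.59 against 8.36 to 10.11. The hypothalamus array labelled congenic 2-choice held the highest Alb (11.42) and Apoa1 (11.12) of the hypothalamus arrays. Errors are standard errors (SE) of the fitted log2 difference, and no pool was repeated.

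The first question of the design was which genes differ between the congenic strain and B6, as candidates for nutrient intake on chromosome 17. Of the 20 genes named by rule in liver, 8 lay on chromosome 17, 2 of the 10 higher and 6 of the 10 lower in the congenic pools. Decr2, a peroxisomal enzyme of unsaturated fatty acid oxidation, was 5.57-fold lower in the congenic pools (log2 -2.48 ± 0.85 SE), by -2.63 on chow and -2.32 on 2-choice. SEs of this fit come from both tissues, so they also hold the spread between the hypothalamus pairs. For Decr2 the hypothalamus pairs, as labelled, were far apart, at 1.38 on chow and -3.26 on 2-choice. Cyp39a1, an oxysterol hydroxylase of bile acid synthesis, was 7.28-fold lower (log2 -2.86 ± 0.58), and Tiam2, an activator of Rac, 10.1-fold lower (log2 -3.34 ± 0.62). H2-Ea, the class II alpha chain that C57BL/6 mice lack because of a promoter deletion, was at 8.39 and 8.52 in the B6 livers, under the filter level of 9.04, and at 11.35 and 12.62 in the congenic livers. Its fitted log2 difference was 3.53 ± 0.62, a size that depends on values near the floor.

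None of these passed: limma called 0 of 19807 probes in liver (lowest adjusted p 0.217), with 1318 at an unadjusted p under 0.05. These p-values rest on the error shared with hypothalamus, so the lack of calls does not describe the liver pairs alone. Apod, a lipid carrier, had the lowest p of the named genes that were higher in the congenic liver (log2 2.73 ± 0.33, adjusted p = 0.217). Among the 20 named genes the other 7 lower ones were 1700001C19Rik (log2 -4.11 ± 0.60), Adgrf1 (-2.46), Klhl5 (-2.43), Nxph3 (-2.42), Dock2 (-2.40), Tubb4a (-2.36) and Lrrtm4 (-2.34). The others higher were Zfp945 (2.89), Olfr381 (2.89), Scin (2.89), Sypl2 (2.79), Pld5 (2.76) and Knstrn (2.71), with Skida1 (5.34) and Tnni2 (3.95), each of which rested on 1 pair (10.28 and 7.42). The B6 means of all 10 higher genes, and the congenic means of 1700001C19Rik, Adgrf1, Klhl5, Nxph3, Dock2 and Tubb4a, lay under the filter level of 9.04, so the sizes of these differences too depend on values near the floor. Agpat1, an acyltransferase of phospholipid synthesis, differed by -0.70 ± 0.64, the methylglyoxal-detoxifying Glo1 by 0.58 ± 0.40, and the GLP-1 receptor Glp1r by -1.04 ± 0.66 at dim mean levels of 9.19 and 10.23.

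When the spread came from the 4 liver arrays alone (1 residual degree of freedom), limma called 252 probes between strains, 47 higher and 205 lower in the congenic pools. They held 89 genes with a known chromosome, 25 of them among the 500 chromosome 17 genes tested, against 0.692% of the other genes (odds ratio 7.55, 95% interval 4.51 to 12.3, Fisher's exact test, two-sided, p = 1.23e-12), a test added after the data were seen. In that fit Decr2 had an adjusted p of 1.52e-07. Also on chromosome 17 and called there were the fatty acid hydroxylase Cyp4f14 (log2 -1.66 ± 0.15), Apom, the apolipoprotein that carries sphingosine 1-phosphate (-1.57 ± 0.14), the liver-secreted class I gene H2-Q10 (-1.18 ± 0.21) and Cbs, the first enzyme of transsulfuration (0.90 ± 0.16). Genes called there on other chromosomes included Cyp4a14 (-1.21 ± 0.23), A2m (-1.36 ± 0.22) and Acly, the cytosolic citrate lyase of lipogenesis (1.03 ± 0.22).

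The sets of pairs used for chromosome 17, other than all 4 pairs, were chosen after the data were seen. Without any test per gene, 146 of 500 chromosome 17 genes (29.2%) had a mean liver strain difference of at least 1.5-fold with the same sign in both pairs, 59 higher and 87 lower in the congenic pools, against 18.1% of genes elsewhere. The odds ratio was 1.87 (95% interval 1.52 to 2.29, Fisher's exact test, two-sided, p = 4.18e-09; adjusted p = 8.36e-09 over 4 sets of pairs). Those at least 1.5-fold apart in each liver pair were 94 of 500 (18.8%) against 8.93% (odds ratio 2.36, same exact test, p = 3.09e-11), an alternative added after the data were seen. The share by the mean (29.2%) was higher than on the other 19 chromosomes, of which 7 and X had the next shares (23.9% each). Along the chromosome, the bin from Zfand3 to Olfr126, which holds much of the major histocompatibility complex, had 46 of 133 genes apart (34.6%, adjusted p = 7.2e-05). The next bins had 22 of 66 from Crisp3 to Rftn1 (33.3%, adjusted p = 0.00835) and 21 of 49 from Plcl2 to Nudt12 (42.9%, adjusted p = 2.74e-04). The first bin, from H2-Q8 to Prr18, had 9 of 17 genes apart (same exact test, adjusted p = 0.0042). H2-Q8, one of the 9, stands far from H2-Q10 in the gene order used, so its place in this bin is doubtful. Bins between Fer and Rmdn2 had 3 of 39, with no bin there passing (same exact test, adjusted p of 0.701 and 0.357). Before Zfand3, the bins from Qk to Fpr2 (5 of 21, 23.8%) and from Fpr-rs6 to Cmtr1 (31 of 138, 22.5%) did not pass (adjusted p of 0.63 and 0.357). Nor did the bins after Rmdn2 (adjusted p of 0.63 and 0.47).

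**Figure D1:**
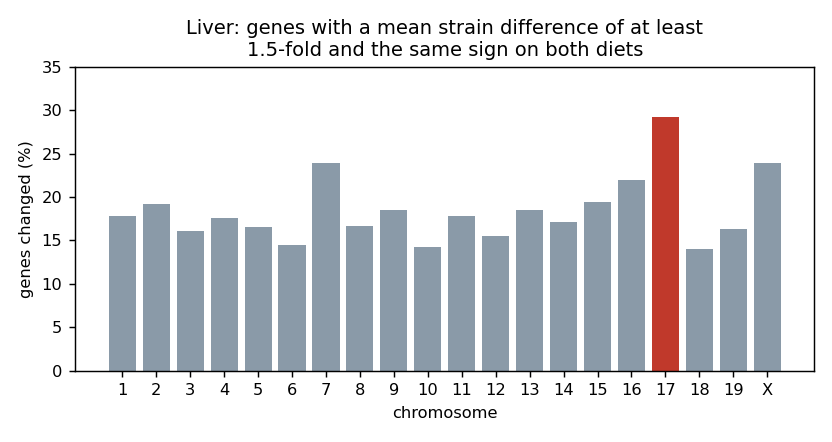
Bars show, for each chromosome on the horizontal axis, the percent of tested genes whose mean difference between congenic and B6 liver was at least 1.5-fold, with the same sign on both diets. Chromosome 17 (red) stands at 29.2% and chromosomes 7 and X, the next, at 23.9%.

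Fixed lists gave no call for the liver strain difference with camera over 37 lists. The lowest adjusted p values were 0.051 for cytosolic ribosomal proteins (15 of 27 measured members higher in both congenic pools, 5 lower) and 0.0525 for amino acid breakdown and urea cycle (11 of 19 higher, 2 lower). With an estimated correlation both had adjusted p = 0.894. Adjusted over the list alone, Cbs (adjusted p = 0.00984) and the aspartate aminotransferase Got1 (log2 0.61 ± 0.15, adjusted p = 0.0334) passed in the latter list. In the class II list, H2-Ea and H2-Oa (log2 1.55 ± 0.52) were higher and H2-Aa (-1.78 ± 0.58) lower, adjusted over the list alone (adjusted p = 0.00356, 0.0473 and 0.0473), while the other 5 members did not pass.

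In hypothalamus the strain difference depended on which diet pair was read. Decr2 was -3.26 in the 2-choice pair and 1.38 in the chow pair, as labelled. Cyp4f14 was -2.96 and 2.69, Agpat1 -0.98 and 2.29, and Glo1 0.71 and -1.37. In these 4 genes, of which Cyp4f14 was picked after its values were seen, the 2-choice pair had the sign seen in both liver pairs and the chow pair, as labelled, had the other. Glp1r did not follow them, at 0.07 in the 2-choice pair and 0.93 in the chow pair against -0.29 and -1.79 in liver. limma called 0 of 19807 probes (lowest adjusted p 0.203, 983 at an unadjusted p under 0.05). The lowest p belonged to Perp, a desmosomal p53 target (log2 3.25 ± 0.36, 3.35 and 3.16 in the pairs), which did not pass. Of the other named genes, with a higher mean and the same sign in both pairs, without passing, were Ttc24 (4.06), Akr1c14 (3.82), Acap1 (2.83), Samt3 (2.77), Rexo5 (2.62), Abi3bp (2.55), Spp2 (2.50), Ccdc121 (2.49) and Il4 (2.41). Lower were Cdx4 (-3.88), Cxcl11 (-2.74), Tnpo1 (-2.64), Abhd14a (-2.60), Metap2 (-2.56), Olfr1104 (-2.46), Ttc17 (-2.46), Cyp2d22 (-2.43), Rab32 (-2.37) and Cbl (-2.32). Several means rested on 1 pair: the chow and 2-choice pairs gave -7.12 and -0.64 for Cdx4, -5.05 and -0.16 for Abhd14a, -4.94 and -0.17 for Metap2, -4.85 and -0.07 for Ttc17, -4.73 and -0.13 for Cyp2d22, -0.50 and -4.43 for Olfr1104, 7.45 and 0.67 for Ttc24 and 4.49 and 0.51 for Spp2. The B6 means of the higher genes other than Spp2, and the congenic means of Cdx4, Cxcl11, Tnpo1, Olfr1104, Rab32 and Cbl, lay under the filter level of 9.26, so the sizes depend on values near the floor.

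Feeding peptides gave no strain call in hypothalamus. Of the 9 measured orexigenic genes, 2 were higher and 1 lower in both congenic pools (camera adjusted p = 0.942 over 28 lists), with Npy at -0.44 ± 0.52 and Hcrt at 0.57 ± 0.42. Of the 15 anorexigenic genes, 2 were higher and 4 lower (adjusted p = 0.841), among them Pomc at -0.65 ± 0.62. The Crh difference of 2.10 ± 0.96 came from the chow pair (4.28 against -0.08). Agrp and Pmch were not among the probes with a single symbol.

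Across chromosome 17, 426 genes tested in both tissues were compared between pairs, as correlations across genes, which are not independent replicates. The liver pairs correlated at r = 0.515 (rho = 0.436), and the hypothalamus 2-choice pair with the liver chow pair at r = 0.354 (rho = 0.274) and with the liver 2-choice pair at r = 0.235 (rho = 0.164). The hypothalamus chow pair correlated with the hypothalamus 2-choice pair at r = -0.247 (rho = -0.184), below all of 10000 random gene lists matched on level (lowest -0.224). With the liver pairs it correlated at r = -0.049 on chow and -0.106 on 2-choice, where 2473 and 407 of the random lists were as low. With the stricter filter these were -0.126 and -0.209, with 283 and 45 as low. On other chromosomes these correlations were 0.148 between the liver pairs and 0.018 between the hypothalamus pairs. The diet arms of a tissue are separate pools, so no array was shared between pairs.

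**Figure D2:**
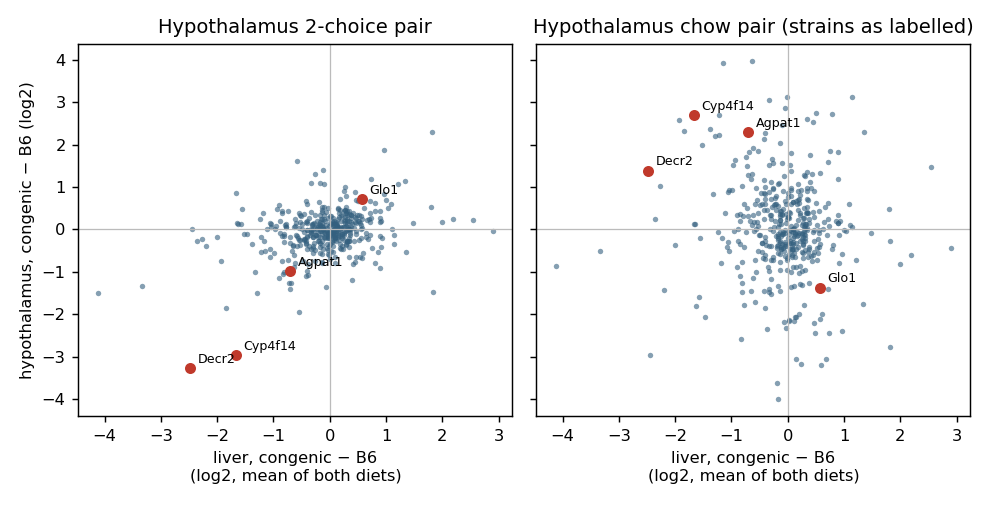
Each point is 1 of 426 chromosome 17 genes, with the mean liver strain difference (congenic minus B6, log2) on the horizontal axis and the hypothalamus strain difference (log2) of the 2-choice pair (left) or of the chow pair as labelled (right) on the vertical axis. Decr2, Cyp4f14, Agpat1 and Glo1 (red) lie on the same side of 0 in both tissues on the left and on opposite sides on the right.

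Over both tissues, limma on the 4 pairs called 0 of 15466 probes (lowest adjusted p 0.466, 660 at an unadjusted p under 0.05). The chromosome 17 share of strain calls therefore rested on no call. The lower named genes were led by 1700001C19Rik (log2 -2.64 ± 0.64), Tiam2 (-2.13 ± 0.59), Tnpo1 (-2.13 ± 0.47) and Adgrf1 (-1.97 ± 0.56, with 8.50 in both hypothalamus 2-choice pools), followed by Pigm, Klhl5, Slc29a3, Zfp398, Kcnk4 and H2-Q8 between -1.78 and -1.55. The genes higher were led by Map3k4, a stress-activated kinase gene of chromosome 17 (1.70 ± 0.52), followed by Letm2, Ush1g, Rp2, Slpi, E2f2, Vmn1r17, Carns1, Pikfyve and Eppk1 between 1.56 and 1.24. All had adjusted p = 0.863. Decr2 was at -1.71 ± 0.66, Glo1 at 0.12 ± 0.32, Agpat1 at -0.02 ± 0.51 and Glp1r at -0.27 ± 0.51.

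Without the hypothalamus chow pair, 9 probes passed, 4 higher and 5 lower, and all 5 of the genes they named lay on chromosome 17. Decr2 (log2 -2.74 ± 0.18, adjusted p = 0.00422), Cyp4f14 (-2.10 ± 0.24, adjusted p = 0.0382), the general transcription factor gene Taf11 (-1.84 ± 0.15, adjusted p = 0.00856) and the ribonuclease gene Rnaset2b (-1.36 ± 0.11, adjusted p = 0.00856) were lower in the congenic pools, and the dynein light chain gene Dynlt1b was higher (1.27 ± 0.12, adjusted p = 0.0132). Leaving out any other pair gave 0 calls. Over those 3 pairs 67 of 426 chromosome 17 genes (15.7%) had a mean difference of at least 1.5-fold with the same sign in each, against 6.14% elsewhere (odds ratio 2.85, 95% interval 2.13 to 3.78, Fisher's exact test, two-sided, p = 1.6e-11). Those 1.5-fold apart in each of the 3 pairs were 20 of 426 (4.69%) against 0.707% (same exact test, p = 7.37e-10). By the same exact test on the mean it was 27 of 426 (6.34%) against 4.33% in all 4 pairs (p = 0.0534), and in the hypothalamus pairs, with the chow pair as labelled, 79 of 481 (16.4%) against 17.1% (p = 0.756). In the hypothalamus 2-choice pair alone it was 90 of 481 (18.7%) against 10.6% (same exact test, p = 2.82e-07), and in the chow pair alone, where no sign enters, 239 (49.7%) against 45.5% (p = 0.0825).

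Among 22 lists tested over both tissues, oxidative phosphorylation (28 measured, 4 higher in all 4 congenic pools and 1 lower, median log2 0.11, camera adjusted p = 0.0458) and cytosolic ribosomal proteins (27 measured, 6 higher and 1 lower, median 0.12, adjusted p = 0.0472) rose. Both had adjusted p = 0.592 with an estimated correlation. Examples were Cox7c (0.36 ± 0.11) and Rpl12 (0.39 ± 0.11), and no member passed, also when adjusted over the list alone. Without the hypothalamus chow pair oxidative phosphorylation had a camera adjusted p of 0.483, while cytosolic ribosomal proteins (0.00132), MHC class II (0.0125) and hepatocyte markers (0.0219) passed. An estimated correlation was not run for that fit, and the direction of the lists was not recorded. The test of strain by tissue called 0 of 15466 probes (lowest adjusted p 0.796, 836 at an unadjusted p under 0.05), so no gene was shown to differ between strains by unequal amounts in the tissues.

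The second question was how the choice of diets moved expression against chow. In liver, 14 of 18 measured lipogenesis genes were higher in the 2-choice pools of both strains, while Scd2 was lower in both and Scd1, Gpam and Slc25a1 were split. Fasn, the fatty acid synthase, was 1.27 ± 0.24 log2 units higher, Thrsp, a regulator of lipogenesis, 1.17 ± 0.18, and the citrate lyase Acly 1.10 ± 0.31. G6pc, the glucose-6-phosphatase catalytic subunit, was 1.71 ± 0.24 higher, by 1.49 in B6 and 1.94 in the congenic pool. The fixed gluconeogenesis list was not among the lists that passed in liver. Oat, the ornithine aminotransferase, was -1.17 ± 0.18, Cyp2c55, a cytochrome P450, -3.34 ± 0.55, and the complement subcomponent C1qb of macrophages -1.86 ± 0.22.

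No single probe passed in liver (limma, 0 of 19807, lowest adjusted p 0.125, 1731 at an unadjusted p under 0.05), while 5 of 37 lists did. Lipogenesis rose (18 measured, 14 higher in both strains and 1 lower, 7 passing when adjusted over the list alone, camera adjusted p = 1.05e-07). Amino acid breakdown and urea cycle fell (12 of 19 lower, 1 higher, 4 passing over the list alone, adjusted p = 0.00191), with Oat, the transsulfuration enzyme gene Cth (-0.87 ± 0.25) and Got1 (-0.59 ± 0.15). Xenobiotic metabolism fell (12 of 22 lower, 4 higher, adjusted p = 0.00609), with Gstm1 (-2.12 ± 0.51), Cyp2b9 (-1.87 ± 0.61) and Cyp2c29 (-1.49 ± 0.25), although Cyp1a1 was higher (1.75 ± 0.52). MHC class II fell (7 of 8 lower, camera adjusted p = 0.00609), with H2-Aa (-1.61 ± 0.58), H2-Ab1 (-1.45 ± 0.64) and Cd74, the invariant chain (-1.29 ± 0.38). The 7 include H2-Ea, whose B6 difference of -0.13 lay between values under the filter level (8.39 and 8.52) and says nothing on direction in B6. Glyoxalase and aldehyde defence fell (13 of 16 lower, adjusted p = 0.0338), with the glutathione synthetase gene Gss (-0.87 ± 0.28) and Hmox1 (-0.77 ± 0.33). With an estimated correlation all 5 had adjusted p = 0.717. The median of each of these lists kept its sign under every scaling.

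**Figure D3:**
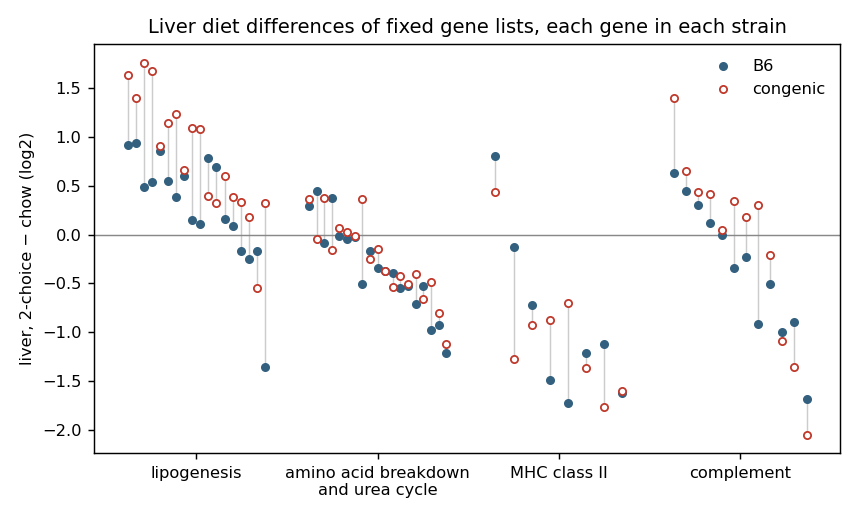
Each pair of points joined by a line is 1 gene of 4 fixed lists, with the liver diet difference (2-choice minus chow, log2) of B6 (filled) and of the congenic strain (open) on the vertical axis and genes ordered by their mean within a list. Lipogenesis genes lie mostly above 0 and MHC class II genes below it, and the 3 lowest complement genes are C1qb, C1qa and C1qc.

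The macrophage and endothelial lists did not pass in liver. Of the macrophage list, Lyz2 was -1.22 ± 0.30 and passed when adjusted over the list alone (adjusted p = 0.0144), while the list itself had no call (2 of 4 lower in both strains, adjusted p = 0.196). Of 9 endothelial markers 4 were lower in both strains and none higher (adjusted p = 0.156), with Pecam1 at -1.20 ± 0.65. C1qb, C1qa (-1.13 ± 0.20) and C1qc (-1.04 ± 0.20) passed when adjusted over the complement list alone, while the list did not pass (of 12 measured, 4 higher and 4 lower in both strains, adjusted p = 0.546). Fatty acid oxidation and PPAR alpha targets showed no common direction (10 of 26 higher, 6 lower, adjusted p = 0.333), with Pdk4 at 1.36 ± 0.75 and Cpt1a at -0.60 ± 0.60. Cholesterol synthesis did not pass (8 of 15 higher, 6 lower, adjusted p = 0.358), with Insig1 and Sc5d each at 0.60 and passing over the list alone (adjusted p = 0.0348).

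Other genes named by rule in liver did not pass either. Higher in both 2-choice pools were Igdcc4 (3.11), Plppr4 (2.80 ± 0.31, adjusted p = 0.125), Dcc (2.65), Cstad (2.59), Chrna4 (2.58), Fmn1 (2.38), Ccdc96 (2.36), Smpd3 (2.35), Guca2a (2.31) and Cyp2ab1 (2.28). Lower were Tnni2 (-4.37), Vps33a (-3.97), Treml4 (-2.96), Skil (-2.83), Lrrc29 (-2.74), Ctnnbl1 (-2.59) and 3 genes of phagocytes and lymphoid tissue, the NADPH oxidase subunit Cybb (-2.65), the receptor Adgre4 (-2.61) and the chemokine Cxcl13 (-2.55). Several of these means rested largely on 1 strain: B6 and congenic gave 0.88 and 5.34 for Igdcc4, 0.63 and 4.54 for Cstad, 0.94 and 3.78 for Ccdc96, -0.91 and -7.83 for Tnni2, -0.82 and -7.12 for Vps33a, -5.07 and -0.58 for Skil and -4.43 and -0.75 for Ctnnbl1. The chow means of all 10 higher genes, and the 2-choice means of Tnni2, Skil, Lrrc29, Cybb, Adgre4 and Cxcl13, lay under the filter level, so the sizes depend on values near the floor. With the spread from the 4 liver arrays alone, limma called 639 probes, 340 higher and 299 lower. Fasn (± 0.16, adjusted p = 2.43e-04), Thrsp, Acly, Oat, C1qb and Cybb were among them.

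In hypothalamus, Gh, the growth hormone gene of pituitary somatotrophs, was higher in the 2-choice pools (log2 4.77 ± 0.76, adjusted p = 0.0443), by 6.04 in B6 and 3.50 in the congenic strain. Its chow levels of 8.28 and 8.74 lay under the filter level of 9.26, as did the chow means of Zfp992, Lrfn5, Lsm5, Psmb5 and Txnrd1, so the sizes of these differences depend on values near the floor. Cga, the glycoprotein hormone alpha subunit (3.93 ± 0.68, adjusted p = 0.051), and Prl, prolactin (3.13 ± 0.66, adjusted p = 0.0718), were higher as well without passing. The zinc finger gene Zfp992 (4.82 ± 0.35), the synaptic adhesion gene Lrfn5 (4.12 ± 0.66), the RNA-processing gene Lsm5 (3.76 ± 0.54), the proteasome subunit gene Psmb5 (3.47 ± 0.52), the thioredoxin reductase gene Txnrd1 (2.44 ± 0.38) and the cytochrome oxidase assembly gene Cox19 (2.38 ± 0.36) rose, with adjusted p between 0.00499 and 0.0443. Ulk4 (-2.10 ± 0.18), Abhd15 (-1.86 ± 0.31), Pam, which amidates neuropeptides (-1.37 ± 0.22), Cog6 (-1.35 ± 0.20), Pdia5 (-1.22 ± 0.19), Rnpepl1 (-1.19 ± 0.18) and the gamma-secretase subunit gene Psenen (-1.05 ± 0.16) fell, with adjusted p between 0.00721 and 0.0471. On the values as deposited all of these but Abhd15 were positive, though below the median of all genes tested there.

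limma called 97 of 19807 probes, 70 higher and 27 lower, with 54 named, and 4143 at an unadjusted p under 0.05. With a variance model that has no trend on level, limma called 0. The median diet difference of all genes tested was 0.11 here and 2.12 as deposited, a scaling under which 15377 of 15430 calls were higher. With arrays shifted to a common median, 7167 of 7633 were. Of the 97 calls 35 (36.1%) lay on probes over 16-fold brighter in liver, against 2.34% of the probes tested, and 3 of these 35 kept their call with the spread of the hypothalamus arrays alone. The 35 included Ttpa (2.99), which kept its call, and Ttr (2.56), Cth (2.48), Papss2 (2.34), Cyp2c29 (2.32), Hsd3b7 (2.26), Upp2 (2.25) and Man1a (2.23), higher in the 2-choice pools. Cyp3a41a (-2.49), Baat (-2.39), Hp (-2.09), Gnmt (-1.78), Slc38a4 (-1.77), Fetub (-1.48) and Proc (-1.33) were lower. The chow means of Ttpa, Cth, Papss2, Cyp2c29, Hsd3b7 and Man1a, and the 2-choice means of Cyp3a41a, Baat, Hp, Gnmt, Fetub and Proc, lay under the filter level, so these sizes depend on values near the floor. Of the other 62 calls 58 kept theirs.

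Of 28 lists in hypothalamus, cytosolic ribosomal proteins fell with diet (14 of 28 measured lower in both strains, 6 higher, median log2 -0.27, camera adjusted p = 0.0265), with Rplp0 (-0.91 ± 0.16) passing over the list alone. With an estimated correlation the adjusted p was 0.784, and the list's median was 1.64 on the values as deposited, below the 2.12 of all genes tested there. Orexigenic genes (4 of 9 higher, 2 lower) and anorexigenic genes (5 of 15 higher, none lower) did not pass (both adjusted p = 0.602). Among their members Bdnf, a neurotrophin that limits intake, was 2.80 ± 0.71 higher, Hcrtr1 1.68 ± 0.63 and Hcrt 0.83 ± 0.42, and Npy was at -0.56 ± 0.52, none passing. Hepatocyte markers (4 of 7 higher, adjusted p = 0.0786) and pituitary markers (4 of 6 higher, 1 lower, adjusted p = 0.115) did not pass. Alb was 0.60 higher in B6 and 2.61 higher in the congenic 2-choice pool.

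Over both tissues no probe passed for diet (limma, 0 of 15466, lowest adjusted p 0.130, 1491 at an unadjusted p under 0.05). The complement list passed as lower (3 of 4 measured lower in all 4 pairs, camera adjusted p = 4.75e-04, and 0.909 with an estimated correlation). Only these 4 of the 17 genes on the list were tested in both tissues, so the result does not describe complement as a whole. Without a filter the camera adjusted p was 0.0549. The list did not pass within hypothalamus (4 measured, camera adjusted p = 0.115). Nor did it within liver (12 measured, 4 higher and 4 lower in both strains, camera adjusted p = 0.546). C1qa (-0.91 ± 0.17), C1qb (-0.97 ± 0.34) and C1qc (-0.71 ± 0.21) made up 3 of the 4 and passed when adjusted over the list alone. In liver they were at -1.13, -1.86 and -1.04, so their means over both tissues rested more on liver. The median of the 4 genes was -0.81 here and 0.24 as deposited. The median of all genes tested went from 0.04 to 1.05, so that of the 4 lay below it under both. The test of diet by tissue called 10 probes, 1 higher and 9 lower in liver minus hypothalamus. Cyp2c29, Cth, Ttr, Gstm2, Upp2 and Oat were named among the lower and Hp, the haptoglobin gene, was the higher. Without a trend limma called 0 and with a stricter filter 2. Leaving out 1 array leaves its tissue no residual, so the spread then comes from the other tissue alone. Most of the 10 calls were lost where the spread came from hypothalamus. Calls kept where it came from liver say nothing on stability. Gstm2, for example, was 2.08 and 2.25 higher with diet in hypothalamus and -1.22 and -0.89 in liver.

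Strain by diet within a tissue had 1 pool per combination and was not tested. The strain difference of the chow pair had an SD of 1.27 over hypothalamus probes and that of the 2-choice pair 0.499, and 34.2% and 5.29% of probes were at least 2-fold apart. In liver the SDs were 0.868 on chow and 0.841 on 2-choice. The largest single-pool strain differences in the hypothalamus 2-choice pair were 4931417E11Rik (4.93), Il4 (3.62), Pcid2 (3.58), Saa4 (3.45) and Perp (3.16), and, lower, Olfr1104 (-4.43), Rnf123 (-3.52), Decr2 (-3.26), Mcm3ap (-3.04) and Cyp4f14 (-2.96). In the chow pair they were Olfml2a (7.98), Ttc24 (7.45) and Akr1c14 (6.48) and, lower, Fgd3 (-7.20), 1700010D01Rik (-7.16) and Cdx4 (-7.12). In liver they reached 10.28 for Skida1 and -8.00 for Tex48 on 2-choice, and 9.06 for Sprr2j-ps and -4.40 for 1700001C19Rik on chow. The difference of the strain differences between diets was -5.65 for Cyp4f14 in hypothalamus. Saa4 was at 16.62 to 17.25 in the livers. Its highest hypothalamus value (11.86) was in the congenic 2-choice array, which also held the highest Alb and Apoa1 of the hypothalamus arrays. More liver RNA in that 1 pool was not tested.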

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

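The tests of exchanged arrays, noise and a diet-dependent strain effect, and that of added liver RNA, were chosen only after the result was seen. On chromosome 17 the strain differences of the hypothalamus chow pair, as labelled, ran against those of the 2-choice pair (r = -0.247 across 426 genes), a difference between the diet groups. Over the 67 chromosome 17 genes with a mean difference of 1.5-fold and the same sign in the other 3 pairs, the median of the chow pair, signed by the other pairs, was -0.58 (95% bootstrap interval -0.88 to -0.14) with 45 genes opposite, against -0.02 over 478 genes elsewhere, which argues against noise that is independent between genes. The intervals here resample genes, which are not independent replicates, and do not cover the spread between pools. Noise shared by many genes of 1 pool is therefore not covered. Exchanged strain labels of the 2 chow arrays may account for the opposite signs. The free-text description of the array labelled congenic names C57BL/6J, though descriptions of other samples also differ from their titles. By at least 1.5-fold, 33 of the 67 genes were opposite in the chow pair and 13 went the same way. The array labelled B6 lay 0.38 (0.16 to 0.66) toward the congenic side of the 2-choice mean. The array labelled congenic lay -0.27 (-0.65 to 0.00) toward the B6 side. A stricter version, run first, that asked both intervals to lie clear of 0 was therefore not met. Over the 20 genes 1.5-fold apart in each of the other 3 pairs the 2 arrays lay at 0.57 (0.29 to 0.84) and -0.69 (-1.15 to -0.11). Of these genes 16 were opposite in the chow pair. That pair's correlations with the liver pairs were weak (-0.049 and -0.106, and -0.126 and -0.209 with the stricter filter). A strain effect that depends on the diet, with the same 45 genes opposite, cannot be told apart from an exchange with 1 pool per strain and diet.

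Diet effects differed between tissues for 7 named genes by the test of the difference itself, as liver minus hypothalamus. These calls fell to 0 without a trend on level and 2 with a stricter filter. Most of the 10 were lost without 1 liver array, where the spread came from hypothalamus alone. Without 1 hypothalamus array it came from liver alone, so calls kept there say nothing on stability. The 7 genes were Cyp2c29 (-3.81), Cth (-3.34), Ttr (-3.28), Gstm2 (-3.22), Upp2 (-2.81), Oat (-2.14) and Hp (2.34). All but Oat were also hypothalamus diet calls on probes over 16-fold brighter in liver. With the spread of the hypothalamus arrays alone, Gstm2 kept that call (limma adjusted p = 0.0404). Cyp2c29, Cth, Ttr, Upp2 and Hp lost it (limma adjusted p of 0.0667 to 0.187). Of the 35 hypothalamus diet calls on probes over 16-fold brighter in liver, 3 kept their call when the spread came from the hypothalamus arrays alone, and their median SE went from 0.233 to 0.861, which is consistent with a spread set by the bright liver values. More liver RNA in the pools of 1 diet would move these probes 1 way, and 9 of the 35 went against the other 26. A diet effect on such genes in hypothalamus was not tested apart from this.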

How the results depend on the processing

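The sets of pairs for chromosome 17, the count with 1.5-fold in each pair and the list tests on a tissue alone or without the hypothalamus chow pair were chosen only after the data were seen. With the spread from the tissue alone, limma called 21 probes between strains in hypothalamus and 252 in liver, and 753 and 639 for diet. As deposited and with a common median, strain in hypothalamus had 1 and 1, diet in hypothalamus 15430 and 7633, and diet by tissue 10781 and 3901; diet over both tissues had 5 as deposited. Diet in hypothalamus had 43 with a stricter filter, 173 with robust fitting and 0 without a trend (limma; 4143 at an unadjusted p under 0.05 with it), and diet by tissue 2 and 0 with the stricter filter and without a trend. As deposited, Ulk4 (0.053), Pam (0.635), Cog6 (0.862), Pdia5 (1.033), Rnpepl1 (0.973) and Psenen (1.008) turned positive, by construction of the shift of all genes between pairs (median 2.12). Chromosome 17 genes with a mean of at least 1.5-fold and 1 sign numbered 27 in all 4 pairs, 146 in the liver pairs, 79 in the hypothalamus pairs, 67 without hypothalamus chow (3, 94, 19 and 20 with 1.5-fold in each pair), and 239, 90, 204 and 189 in hypothalamus chow, hypothalamus 2-choice, liver chow and liver 2-choice alone. With an estimated correlation and with fry, 0 lists passed for strain over both tissues and for diet over both tissues, in hypothalamus and in liver. Without a filter 2 lists passed for strain in liver, 0 for diet over both tissues and 2 for diet in hypothalamus, and on the tissue alone 5 for strain in liver and 3 for diet in hypothalamus. Leaving out arrays or pairs gave 0 to 9 calls for strain over both tissues, 33 to 1376 in hypothalamus, 10 to 24 in liver and 3 to 810 for strain by tissue. For diet it gave 0 to 2 over both tissues, 713 to 1714 in hypothalamus, 9 to 28 in liver and 4 to 1292 for diet by tissue. The hypothalamus strain difference then ranged from -3.26 to 1.376 for Decr2, from -1.37 to 0.706 for Glo1 and from -0.985 to 2.29 for Agpat1, as the pairs differ. Fits per tissue or by tissue without 1 array keep no residual in that tissue, so their spread comes from the other tissue alone. Their counts say nothing on stability, and the lone array is assumed to vary like the others. Other causes were not tested. The values of the named genes that did not pass say little on stability, since these genes were named for 1 sign in every pair. Of the called genes, diet in hypothalamus kept direction and side of the threshold in 284 of 362 values. The 362 include the fits without 1 array, so this share says little on stability either. Signal near background limits the dim probes, for which no detection flag was used.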

Other observations

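The liver genes named first and the neuronal genes were chosen after their values were seen, and the tests of pituitary tissue and of sensitivity and the counts of splits were fixed before their results. In the fit on the 4 liver arrays alone, which has 1 residual degree of freedom, Vsig4 (log2 -2.19 ± 0.26, adjusted p = 1.63e-04), Cd5l (-1.47 ± 0.14), Folr2 (-1.38 ± 0.22), Clec4f (-1.33 ± 0.15) and Timd4 (-0.94 ± 0.23), each known from macrophages, were lower in the 2-choice pools. Gpr182 (-1.57 ± 0.29), Fcgr2b (-1.57 ± 0.20), Clec4g (-1.06 ± 0.19) and Plvap (-1.02 ± 0.19), known from endothelium, were lower too. No group is claimed from these picks, and the fixed macrophage and endothelial lists did not pass (adjusted p = 0.196 and 0.156). The haemoglobin gene Hba-a1 was lower (-1.27 ± 0.17), as was Alas1, the first enzyme of haem synthesis (-1.38 ± 0.16). Apoa4, an apolipoprotein (1.40 ± 0.15), Ppp1r3b, a glycogen-targeting phosphatase subunit (1.30 ± 0.14), the elongase gene Elovl6 (0.80 ± 0.17) and Srebf1, a regulator of lipogenesis (0.63 ± 0.15), were higher.

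Gnao1 was at 10.51 and 10.79 in B6 liver and at 8.51 and 8.79 in congenic liver, and Nnat at 10.29 and 10.19 against 8.94 and 7.70. Nrgn (9.62 and 9.9 against 8.61 and 8.57) and Slc32a1 (11.98 and 10.9 against 10.46 and 8.41) went the same way. The congenic values of Gnao1, Nnat and Nrgn lay under the filter level of 9.04, so these sizes depend on values near the floor. Mbp, a myelin gene, went the other way (8.10 and 8.80 against 8.53 and 10.12), and the fixed list of striatum and cortex markers did not pass for strain in liver (adjusted p = 0.488).

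Pituitary hormone transcripts Gh, Cga and Prl were brighter in both 2-choice hypothalamus pools, by 2.46 to 6.04, and Pomc, which hypothalamus also expresses, by 0.26 and 0.41. Of the other measured pituitary genes, 0 of 2 were brighter by 1.5-fold in both strains, the outcome set beforehand as speaking against pituitary tissue taken with the 2-choice pools. That outcome was not met by more than its spread, since Lhb went by -0.42 and -0.45 but Tshb by -0.81 and 1.23 at levels near the filter, and this reading was settled after the values were seen. Over all 5 other list genes on the array, 3 of them under the filter, 1 was brighter, Pitx1 (2.95 and 1.10), so pituitary tissue stays open. Higher sensitivity of the 2-choice arrays to dim probes was tested on 4810 probes as dim on chow as Gh. Of these, 0 were brighter by 3.50 or more in both strains. The values had been quantile normalized, which removes a gain common to many probes, so the test cannot decide on a broad gain. Dimmer on chow than the probes of this test, Zfp992 (5.06 in B6 and 4.58 in the congenic strain) and Lrfn5 (3.56 and 4.68) rose by more than 3.50.

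Splits of the 8 arrays say nothing about chance for the effects over both tissues, because the real split called 0 probes and any split calls as many: 32 of 32 for strain, with 6 the highest other, and 32 of 32 for diet. The highest other for diet was 58, in a split that parts 2 of the pairs, where the real one parts 4.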
